A study of Homo sapiens with 40 samples.

How the data were processed

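RNA of 2 human cell lines, OCI-Ly3 and OCI-Ly10, was measured on 40 spotted 2-colour arrays. Both are established lines of the activated B cell-like form of diffuse large B cell lymphoma, in which NF-kB and STAT3 are commonly active. Per the labels, RNA was prepared with Trizol and copied from an oligo-dT primer, the Cy5 channel held the treated cells and the Cy3 channel held untreated or mock-treated cells of the same line. The 6 experiments were IL-6 at 50 ng/ml in OCI-Ly10 (0.5, 1, 3, 6 and 24 h, 8 arrays), a doxycycline-inducible IkB super-repressor in OCI-Ly3 (20 ng/ml, 1 to 6 h, 9 arrays) and in OCI-Ly10 (1.5, 3, 6 and 24 h, 4 arrays), IL-10 at 50 ng/ml in OCI-Ly3 (1 to 96 h, 10 arrays), STAT3 siRNA at 4 uM against no siRNA in OCI-Ly10 (8, 24 and 48 h, 5 arrays) and JAK inhibitor I at 5 uM in OCI-Ly10 (3 and 6 h, 4 arrays). The super-repressor is a form of the inhibitor IkB alpha that resists degradation and so blocks NF-kB. No array here measured a non-targeting siRNA, or doxycycline in cells without the super-repressor. Effects of siRNA as such, or of doxycycline itself, therefore cannot be told from those of the intended target.

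The deposited values were log ratios of Cy5 over Cy3, read as log2. The base is not stated; the range of -7.868 to 5.81 rules out base 10, while base 2 and the natural base could not be separated, so each log2 value below holds only under base 2. Array medians lay between -0.031 and 0.011, so the authors had centred the arrays; background correction, spot filter and normalization method are not given in the sources used here. Of all cells, 12.6% were blank, and 8862 to 14947 of 15246 probes had a value on an array. Channel intensities were not used here, so signal over background could not be given.

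Each array was median-centred, and probes with 1 gene symbol (10169) were averaged per gene, which gave 4604 genes; 5073 probes with no symbol listed and 4 with several were left out of the gene tests. With limma 3.58.1 in R 4.3.3, 1 mean was fitted per experiment and time point over all 40 arrays, and the average over a window of time points was tested against 0 with moderated statistics and Benjamini-Hochberg adjustment (threshold 0.05). A gene was tested if at least 75% of the window's arrays and every time point had a value. Windows were 2 to 6 h for the super-repressor in OCI-Ly3 (7 arrays), 3 to 24 h in OCI-Ly10 (3 arrays), 1 to 24 h for IL-6 (7 arrays), 1 to 96 h for IL-10 (10 arrays), 24 and 48 h for the siRNA (4 arrays) and 3 and 6 h for the inhibitor (4 arrays). Differences between experiments were tested in the same fit at shared times. A test of a ratio against 0 leaves out the spread of the control RNA. There was no dye swap, so a gene's own dye bias stays in its ratio, and the labels do not say whether arrays shared control RNA. Nor do they say whether replicates were separate cultures, so p-values measure only the spread between these samples.

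Windows, tests, alternatives, 20 gene lists and the rule for named genes were fixed before the data were examined. The rule takes, per experiment, the 8 highest and 8 lowest called genes with 1 sign on every measured array, up to 2 called members of each list, and STAT3, NFKBIA, IL6, IL10 and SOCS3. The lists covered NF-kB targets, STAT3 targets and JAK-STAT feedback, interferon-stimulated genes, JAK, STAT and cytokine receptor genes, plasma cell differentiation, B cell and germinal centre identity, MHC class II, cell cycle, glycolysis and hypoxia, the BCL2 family, MYC-linked ribosome biogenesis, cytosolic ribosomal proteins, heat shock, immediate-early genes, p53 targets, sterol biosynthesis, chemokines and cytokines, and markers of T and NK cells, of myeloid cells and of erythroid and stromal cells. Each was compared with all other genes by limma's cameraPR at a preset correlation of 0.01 and again with a correlation estimated from the residuals, adjusted over the lists of an experiment. Of 120 list tests, 26 passed with the preset correlation and 5 with an estimated one.

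Array identifiers in the titles fell into 12 consecutive runs (a gap above 50 starts a new one), which the labels do not describe. The median correlation across probes between arrays of an experiment was 0.46 within a run and 0.294 between runs, and all 14 pairs of replicates lay in different runs. Counts with the run as a random block (consensus correlation 0.2687), an alternative chosen after seeing the data, therefore stand beside counts that it moves by over 1.5 times. No time point had 2 arrays in 1 run, so a fit with 1 mean per time point leaves no residual degrees of freedom within a run, and correlations between runs are given instead. For a time point with 1 array, the spread in a test comes only from other time points and experiments. The differences between replicates 2 and 1 correlated across time points at 0.376 to 0.577 for IL-10 and at 0.193 to 0.269 for IL-6. For the super-repressor in OCI-Ly3 the values ran from -0.319 to 0.32, and the siRNA and the inhibitor had 1 such value each (0.299 and 0.203). Replicate numbers followed the runs, so a pairing of samples by number cannot be told from the run. Direction was checked on STAT3, which was below 0 on 5 of 5 siRNA arrays; of 780 pairs of arrays, 8 correlated under -0.3 (lowest -0.4153), none within 1 experiment, so no array was turned.

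The fit was tested on simulated data with the missing values of these arrays. With independent noise 3 to 8.45% of calls were false, and 42 to 97% of genes changed by 0.5 log2 and 88 to 100% of those changed by 1 log2 were recovered. With noise shared within a run, 10 to 25.2% of calls were false without the block and 3.7 to 9.32% with it. The simulated noise was independent between genes and held no dye bias, with a single draw per comparison and kind of noise. False calls that a dye bias or correlated genes would add are therefore not counted in these shares. Alternatives left out each array in turn, changed centring, scaling, probe averaging and the filter, weighted arrays, fitted an experiment alone, and tested each experiment against the other 5 or against its earliest time point. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.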

Results

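The arrays address how NF-kB and STAT3 signalling act on gene expression in 2 lymphoma lines. NF-kB was blocked with the IkB super-repressor, IL-6 or IL-10, cytokines that activate STAT3, were added, and STAT3 was lowered with siRNA or the kinases upstream of it were blocked with JAK inhibitor I. Values are mean log2 ratios of treated over control cells (base 2 assumed) ± SE, with p-values adjusted by limma. The siRNA lowered STAT3, the gene it targets. STAT3 was at log2 -1.99 at 8 h (1 array), -1.86 ± 0.56 (SD) at 24 h and -1.31 ± 0.60 (SD) at 48 h (2 arrays each). NFKBIA encodes IkB alpha and is itself transcribed by NF-kB. After doxycycline NFKBIA was at -0.01 at 1 h, -1.06 at 2 h and -2.17 at 6 h in OCI-Ly3. In OCI-Ly10 it was at -0.33 at 1.5 h, -1.10 at 3 h and -0.92 at 24 h. Probes of NFKBIA could also detect the introduced super-repressor, so its values may not show the cells' own gene alone, and the 2 lines may differ in this. Over the tested time windows its probes ranged from -1.84 to -1.30 in OCI-Ly3 and from -1.39 to -0.80 in OCI-Ly10.

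**Figure D1:**
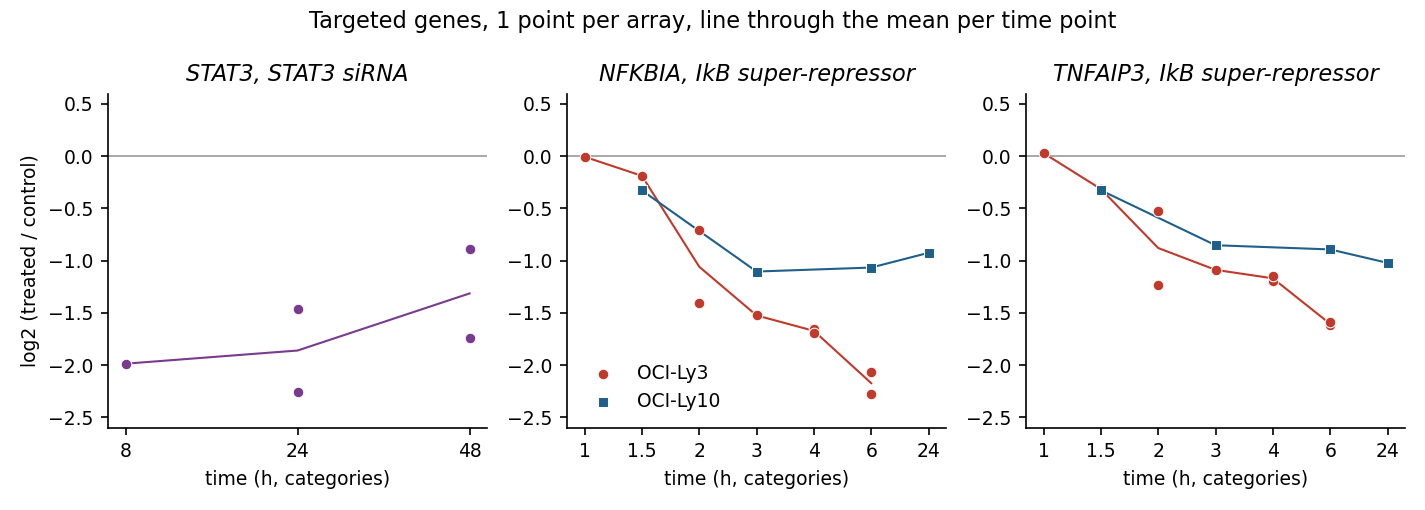
Log2 ratio of treated over control (y axis) against time in hours as categories (x axis) for STAT3 with its siRNA and for NFKBIA and TNFAIP3 with the IkB super-repressor; each point is 1 array and lines join the means per time point. NFKBIA was at -2.17 at 6 h in OCI-Ly3 and at -0.92 at 24 h in OCI-Ly10.

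NF-kB block in OCI-Ly3 lowered the feedback inhibitors of NF-kB and inflammatory cytokine genes. NFKBIA fell by 1.61 ± 0.10 (adjusted p = 1.21e-08) and TNFAIP3, which encodes the deubiquitinase A20, fell by 1.19 ± 0.10 (adjusted p = 2.69e-07). TNF fell by 0.82 ± 0.06 (adjusted p = 1.16e-07) and NFKBIE, another IkB gene, fell by 0.73 ± 0.09 (adjusted p = 3.44e-05). These 4 genes were below 0 on 7 of 7 arrays. ICAM1, an adhesion molecule, was at -0.66, MAP3K8, a kinase upstream of ERK, at -0.69, and the survival genes BCL2A1 and CFLAR at -0.36 and -0.38. Of 40 measured NF-kB targets, 23 fell and 0 rose (28 and 0 adjusted over the list alone; 15 and 0 with the run as a block). As a list they passed at adjusted p = 1.02e-16 with the preset and adjusted p = 0.00626 with an estimated correlation. Of 35 chemokines and cytokines 9 fell and 1 rose (12 and 1 adjusted over the list alone; 2 and 0 with the run as a block). Their list had adjusted p = 5e-06 with the preset and adjusted p = 2.14e-07 with an estimated correlation. Among them, the interferon-inducible chemokine CXCL10 fell by 0.72 ± 0.09 (adjusted p = 5.67e-05, 6 of 7 arrays). IL6 fell by 0.53 ± 0.12 (adjusted p = 0.00675) and IRF4, a transcription factor of activated B cells and plasma cells, fell by 0.45 ± 0.10 (adjusted p = 0.00702), each on 7 of 7 arrays. PIM2, a survival kinase, fell by 0.64 ± 0.14 (7 of 7). STAT3 itself (-0.26, adjusted p = 0.195), IL10 (-0.20) and SOCS3 (-0.14) did not pass the threshold.

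Genes that rose in OCI-Ly3 included TNFRSF17, the plasma cell receptor BCMA (0.63 ± 0.07, adjusted p = 3.04e-05), and BMP6, a growth factor (0.54 ± 0.06, adjusted p = 2.66e-05). CYTIP (0.59 ± 0.06), the G protein regulator RGS2 (0.50 ± 0.07) and the chemokine receptor CXCR4 (0.42 ± 0.06) rose as well, and all 5 genes were above 0 on 7 of 7 arrays. Of 25 cytosolic ribosomal protein genes 15 rose and 0 fell (17 and 0 adjusted over the list alone; 5 and 0 with the run as a block), RPS29 by 0.42 and RPS16 by 0.38. Their list passed at adjusted p = 4.62e-11, but had adjusted p = 0.115 with an estimated correlation. It also passed at adjusted p = 0.000873 against the other 5 experiments, a test that removes a dye bias common to all of them. That test was run only at the preset correlation. Of 36 cell cycle genes 10 rose and 0 fell (11 and 0 adjusted over the list alone; 4 and 0 with the run as a block). The spindle checkpoint genes MAD2L1 (0.36) and CDC20 (0.32) were among these. The cell cycle list had adjusted p = 5.05e-06, and adjusted p = 0.321 with an estimated correlation. Glycolysis and hypoxia genes, with the glucose transporter SLC2A3 and lactate dehydrogenase LDHA, moved the same way (6 of 23 rose and 0 fell, 6 and 1 adjusted over the list alone; adjusted p = 0.0305; adjusted p = 0.498 with an estimated correlation). So did 3 of 15 genes of the MYC-linked list, LDHA, the polyamine enzyme ODC1 and the cap-binding factor EIF4E (4 adjusted over the list alone; adjusted p = 0.0305; adjusted p = 0.583 with an estimated correlation). Neither of these lists kept a called member with the run as a block, and glycolysis and hypoxia genes had adjusted p = 0.154 against the other 5 experiments. Of 21 T and NK cell markers 2 fell, CD6 by 0.30 and CD5, which is also found on some B cells, by 0.24 (0 adjusted over the list alone; 0 with the run as a block). That list had adjusted p = 0.0305, and adjusted p = 0.209 with an estimated correlation.

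In all, 616 of 4390 genes passed the threshold in OCI-Ly3 (402 higher, 214 lower), and 38 of them had a mean of at least 0.5 in size. With the run as a block 103 passed (73 higher, 30 lower), and fitted on the arrays of this experiment alone 368 passed (190 higher, 178 lower). By time point the counts were 1, 0, 2, 1, 44 and 92 at 1, 1.5, 2, 3, 4 and 6 h; at 1.5 h limma gave 254 genes with unadjusted p under 0.05. The means of the 2 runs correlated at 0.652 across genes. Genes are not independent replicates in this or any correlation below. The count was 957 without replicate 1 of 2 h, 269 without replicate 1 of 6 h, 277 without replicate 2 of 2 h and 284 without replicate 2 of 4 h. The 2 replicates of 2 h correlated at -0.016 across probes, and without both the count was 371. IL6, PIM2, CD5 and CD6 lost their calls with the run as a block (adjusted p = 0.0585, 0.0599, 0.197 and 0.218).

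In OCI-Ly10 the same block lowered CXCL10 and NF-kB feedback genes and raised a chemokine gene, CCL4. CXCL10 fell by 1.22 ± 0.13 (adjusted p = 9.16e-05, 3 of 3 arrays). NFKBIA (-1.03 ± 0.15), TNFAIP3 (-0.92 ± 0.14) and PLEK, a substrate of protein kinase C (-0.66 ± 0.10), fell on 3 of 3 arrays and CCL4 rose by 0.82 ± 0.12 on 3 of 3, each at adjusted p = 0.00269. Of 41 NF-kB targets 9 fell and 1 rose (11 and 2 adjusted over the list alone; 4 and 1 with the run as a block). As a list they had adjusted p = 2.35e-14 with the preset and adjusted p = 0.0169 with an estimated correlation. PIM2, the AP-1 factor BATF (-0.74 ± 0.12) and CFLAR (-0.69 ± 0.12) also fell on 3 of 3 arrays, but lost their calls with the run as a block (adjusted p = 0.236, 0.0537 and 0.0606). BATF rested on probes that differed, from -1.22 to 0.25. The 10 MHC class II genes had a median of 0.075 and passed as a list (adjusted p = 0.00293; adjusted p = 0.0169 with an estimated correlation), although none passed singly (2 adjusted over the list alone). Against the other 5 experiments this list had adjusted p = 0.542 and the opposite direction. Ribosomal protein genes had a median of 0.15 (adjusted p = 1.96e-06; adjusted p = 0.369 with an estimated correlation), with 0 of 25 past the threshold over all genes and 1 adjusted over the list alone, and their list had adjusted p = 0.301 against the other 5 experiments. STAT3 (-0.56 ± 0.19, adjusted p = 0.42) and IL10 (-0.35 ± 0.17, adjusted p = 0.797) were below 0 on 3 of 3 arrays without passing. In all, 24 of 4515 genes passed (10 higher, 14 lower). Of these calls 41.7% were higher, and 52.1% of 238 when arrays were scaled to equal spread. With the run as a block 5 passed: CXCL10, NFKBIA, TNFAIP3, PLEK and CCL4. The count was 1 without the 24 h array and 5 without the 6 h array, and all arrays of this experiment came from 1 run without replicates.

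**Figure D2:**
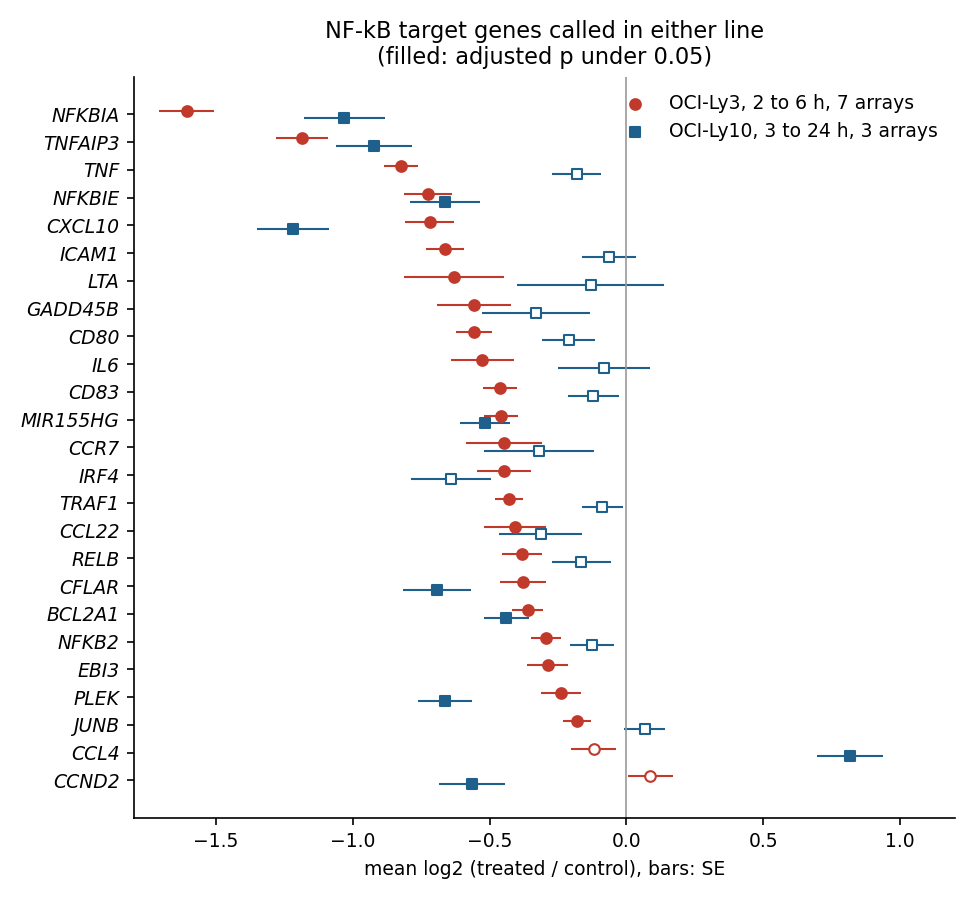
Mean log2 ratio (x axis, bars are SE) of each NF-kB target called in either line under the IkB super-repressor, in OCI-Ly3 (circles, 7 arrays, 2 to 6 h) and OCI-Ly10 (squares, 3 arrays, 3 to 24 h); filled symbols passed adjusted p 0.05. NFKBIA was at -1.61 and -1.03, while CCL4 was at -0.12 in OCI-Ly3 and 0.82 in OCI-Ly10.

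Both lines lowered NFKBIA, TNFAIP3, NFKBIE, CXCL10, PLEK, PIM2, CFLAR, BCL2A1 and the microRNA host gene MIR155HG under NF-kB block (9 genes, where independent lists would share 0.679). TNFRSF17, BMP6, CXCR4, OAS1, ID3, TGIF1, PTPN22 and CCNDBP1 were called higher in both (8 against 0.924), and 0 genes were called in opposite directions. NFKBIA, TNFAIP3 and CXCL10 stayed lower in both with the run as a block (3 against 0.0268), and 0 genes were higher in both. Genes called lower in OCI-Ly3 were low in OCI-Ly10 as a set (210 genes, median -0.072, adjusted p = 1.17e-09; adjusted p = 0.00448 with an estimated correlation). The correlation across 4331 genes was 0.348 (Spearman 0.266), with a jackknife SE over arrays of 0.275 and 0.164 when the 3 h array of OCI-Ly10 was left out. NF-kB block in OCI-Ly10 correlated about as highly with the JAK inhibitor (0.328, Spearman 0.348) and with IL-10 in OCI-Ly3 (0.297, Spearman 0.405). With the experiments outside each pair subtracted, these values were 0.531 between the lines, 0.363 with the inhibitor and 0.196 with IL-10. The same mean is subtracted from both members of a pair, which can raise a correlation by construction. The subtracted experiments also differ between pairs, so these values do not rank the pairs. At the shared times of 1.5, 3 and 6 h, limma called 0 of 4384 genes as differing between the lines (108 with unadjusted p under 0.05, 219.2 expected by chance). TNF differed by -0.55 ± 0.12, ICAM1 by -0.52 ± 0.14 and CCL4 by -0.61 ± 0.16 (OCI-Ly3 minus OCI-Ly10), each at adjusted p = 0.994, the smallest of all. In simulated data this test recovered 42% of genes that differed by 0.5 log2 with independent noise, and 28% with noise shared within a run and the run as a block, so differences of this size are not excluded.

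IL-6 in OCI-Ly10 raised SPP1, GZMB, BCL3 and SOCS3. SPP1, which encodes osteopontin, rose by 1.54 ± 0.15 (adjusted p = 2.44e-05) and GZMB, the cytotoxic protease granzyme B, by 1.05 ± 0.14 (adjusted p = 0.000279), each on 6 of 6 arrays. BCL3, an atypical IkB protein, rose by 0.79 ± 0.07 (adjusted p = 7.85e-06) and SOCS3, the feedback inhibitor of gp130 signalling, by 0.77 ± 0.10 (adjusted p = 0.00026), each on 7 of 7. IL2RB, a subunit of the IL-2 receptor (0.75 ± 0.09), GPR183, an oxysterol receptor that guides B cell migration (0.72 ± 0.10), and PTPN1, a phosphatase that acts on JAK kinases (0.52 ± 0.08), rose on 7 of 7 arrays. SOCS3 was at 2.62 at 30 min (1 array) and 1.46 at 1 h, and BCL3 at 1.19 at 1 h. At 24 h (1 array) SPP1 was at 2.58 and GZMB at 1.98. The IL10 gene was at 1.43 at 30 min (1 array) and 1.22 at 1 h (adjusted p = 0.00852, 2 arrays), with a window mean of 0.16 (adjusted p = 0.46). The 3 probes of SOCS3 differed: 1 gave 1.02 and the other two 0.49. STAT3 (0.075, adjusted p = 0.785) and NFKBIA (0.0011, adjusted p = 0.998) did not pass.

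Genes lower with IL-6 included the interferon-stimulated genes IFI44L (-0.71 ± 0.10, adjusted p = 0.00032) and MX1 (-0.41 ± 0.07, adjusted p = 0.00173), each on 6 of 7 arrays. CCL4 fell by 0.44 ± 0.08 (adjusted p = 0.00453, 5 of 7). TNF fell by 0.41 ± 0.06 (adjusted p = 0.000722, 7 of 7). Of 36 interferon-stimulated genes 4 fell and 0 rose (5 and 0 adjusted over the list alone; 2 and 0 with the run as a block; adjusted p = 0.175). Of 33 STAT3 targets and feedback genes 5 rose and 1 fell (7 and 2 adjusted over the list alone; 3 and 0 with the run as a block). That list passed at adjusted p = 0.00715, but had adjusted p = 0.564 with an estimated correlation. Of 12 T and NK cell markers 2 rose, GZMB and the kinase LCK (3 adjusted over the list alone; 1 with the run as a block). These markers had adjusted p = 0.00715 as a list, and adjusted p = 0.0846 with an estimated correlation. The cell cycle list was lower (median -0.085, adjusted p = 0.00543; adjusted p = 0.704 with an estimated correlation). The ribosomal protein list was higher (median 0.094, adjusted p = 0.0104; adjusted p = 0.725 with an estimated correlation; adjusted p = 0.308 and lower against the other 5 experiments), and 0 members of either list passed singly or adjusted over the list alone. In all, 150 of 3301 genes passed with IL-6 (115 higher, 35 lower). With the replicate number as a block 79 passed, and with the run as a block 32 (27 higher, 5 lower), without LCK (adjusted p = 0.159). Of the calls 76.7% were higher, and 61.8% of 455 when arrays were scaled to equal spread. The 2 runs correlated at 0.44 across genes, and the count was 93 without replicate 2 of 3 h and 97 without replicate 2 of 1 h.

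IL-10 in OCI-Ly3 gave the highest count of called genes in these experiments, with STAT3 itself among them. GPR183 rose by 3.13 ± 0.09 (adjusted p = 6.44e-15) and CXCL9, an interferon-inducible chemokine, by 3.00 ± 0.11 (adjusted p = 2.32e-13), each on 10 of 10 arrays. CD274, which encodes PD-L1, rose by 1.92 ± 0.07 and PRDM1, the plasma cell regulator Blimp-1, by 1.88 ± 0.09 (adjusted p = 4.85e-12), each on 10 of 10. The feedback genes SOCS2 (1.91 ± 0.08) and PTPN1 (1.89 ± 0.07), BCL3 (1.64 ± 0.06), STAT3 (1.37 ± 0.11, adjusted p = 1.45e-08) and the IL10 gene (0.78 ± 0.10, adjusted p = 7.49e-06) rose on 10 of 10 arrays. TNF fell by 1.54 ± 0.05 (adjusted p = 5.56e-14, 10 of 10). LTA, which encodes lymphotoxin alpha, fell by 1.40 ± 0.16 (9 of 9) and CCL22, a chemokine for regulatory T cells, fell by 1.14 ± 0.09 (10 of 10). STAT3 was at 0.16 at 1 h, 2.02 at 3 h and 0.79 at 96 h. PRDM1 was at 0.87 at 1 h and 3.61 at 96 h, and TNF at -0.51 and -2.45 at the same times.

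All 10 measured MHC class II genes rose with IL-10 (10 adjusted over the list alone; 8 with the run as a block). As a list they had adjusted p = 1.1e-09 with the preset and adjusted p = 1.27e-08 with an estimated correlation. HLA-DRA was at 0.12 at 3 h, -0.12 at 6 h, 1.18 at 24 h and 1.72 at 96 h. HLA-DQB1 was at 0.84 ± 0.05, above 0 on 5 of 10 arrays. Of 36 STAT3 targets and feedback genes 21 rose and 5 fell (21 and 6 adjusted over the list alone). Among these were the survival gene MCL1 (0.83 ± 0.05) and BCL6, a transcriptional repressor that germinal centre B cells require (0.54 ± 0.05). Their list had adjusted p = 1.87e-05, and adjusted p = 0.0656 with an estimated correlation. Of 39 interferon-stimulated genes 15 rose and 3 fell (16 and 6 adjusted over the list alone), including the antigen transporter TAP1 (1.09 ± 0.08) and IFITM3 (0.99 ± 0.06). That list had adjusted p = 0.00284, and adjusted p = 0.47 with an estimated correlation. JAK, STAT and receptor genes were higher (9 rose, 3 fell of 20, the same adjusted over the list alone; adjusted p = 0.0124; adjusted p = 0.18 with an estimated correlation). So were immediate-early genes, with JUN at 0.94 ± 0.06 (9 rose, 3 fell of 26, the same adjusted over the list alone; adjusted p = 0.021; adjusted p = 0.288 with an estimated correlation), and ribosomal protein genes (6 of 24 rose, 5 adjusted over the list alone; adjusted p = 0.0299; adjusted p = 0.722 with an estimated correlation, and adjusted p = 0.812 against the other 5 experiments). Of 36 cell cycle genes 16 fell and 2 rose (18 and 2 adjusted over the list alone; 10 and 2 with the run as a block). The mitotic kinase NEK2 fell by 0.73 ± 0.11 (its 2 probes gave -1.41 and -0.079) and the phosphatase CDC25A fell by 0.49 ± 0.06. As a list they had adjusted p = 0.00767, and adjusted p = 0.716 with an estimated correlation. The surface antigens CD38 (-0.73 ± 0.06) and CD24 (-0.71 ± 0.07) fell on 9 of 10 arrays, with CD24 probes from -1.18 to 0.10 and, among the genes above, BCL6 probes from -0.11 to 1.23. NF-kB targets went both ways (14 rose, 11 fell of 42, the same adjusted over the list alone; adjusted p = 0.4), NFKBIA by 0.36 ± 0.09 (9 of 10 arrays). SOCS3 (0.28 ± 0.09, 7 of 10) lost its call with the run as a block (adjusted p = 0.0655), and its probes differed (1.85, measured on 6 arrays, against 0.02 and -0.23).

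In all, 1548 of 4383 genes passed with IL-10 (706 higher, 842 lower), and 243 had a mean of at least 0.5 in size. With the run as a block 1032 passed (500 higher, 532 lower). This window held 10 arrays, the most of the 6 experiments, which also favours a high count. By time point 40, 160, 300, 431, 275 and 663 genes passed at 1, 3, 6, 24, 48 and 96 h, the last 2 times with 1 array each. The 3 runs correlated at 0.369 to 0.57 across genes, and only 1258 of the 1548 called genes had the same sign in all of them, although they were called on the same arrays. The 48 and 96 h arrays formed a run of their own.

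**Figure D3:**
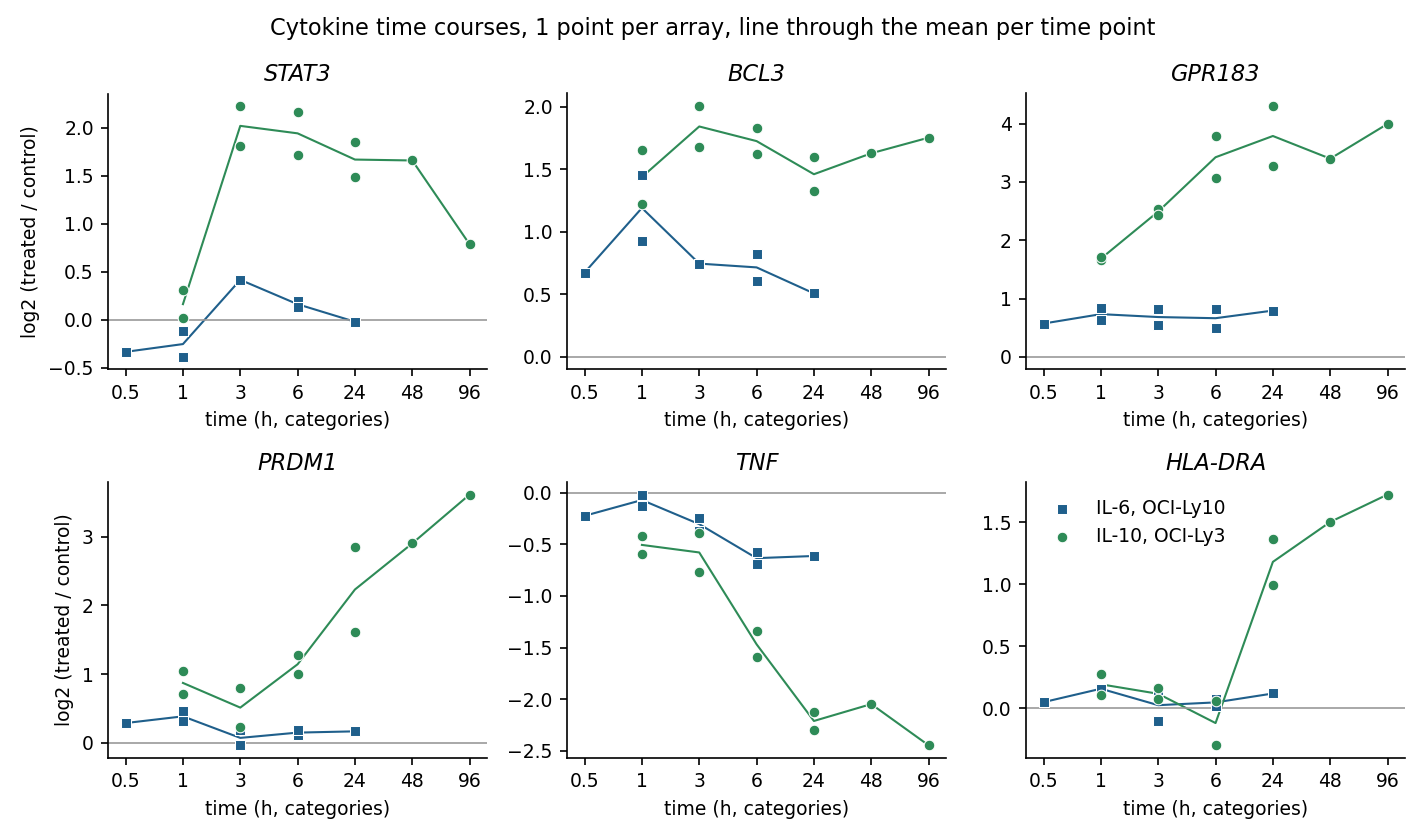
Log2 ratio of treated over control (y axes, each panel with its own scale) against time in hours as categories (x axes) for 6 genes with IL-6 in OCI-Ly10 (squares) and IL-10 in OCI-Ly3 (circles); each point is 1 array and lines join the means. PRDM1 reached 3.61 and TNF -2.45 at 96 h of IL-10, and HLA-DRA was at -0.12 at 6 h and 1.18 at 24 h.

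Set side by side at 1, 3, 6 and 24 h, GPR183, CXCL9, SOCS2 and STAT3 were higher with IL-10 in OCI-Ly3, and SPP1, GZMB and TNF were higher with IL-6 in OCI-Ly10. IL-6 minus IL-10 was -2.13 for GPR183 (adjusted p = 2.21e-08), -1.84 for CXCL9, -1.49 for SOCS2, -1.38 ± 0.18 for STAT3 (adjusted p = 4.48e-05), -1.02 for PTPN1 and -0.83 for BCL3. It was 1.49 for SPP1, 1.09 for GZMB and 0.79 for TNF, which fell less with IL-6. IL2RB differed by 0.06 (adjusted p = 0.818). The called lists of the separate tests overlapped: 39 genes rose with both (22 for independent lists), among them GPR183, BCL3, IL2RB, PTPN1 and JUN, and 18 fell with both (6.56), among them TNF, MX1 and IFI44L. With the run as a block these were 9 (3.71), without JUN, and 3 (0.611), which were TNF, MX1 and IFI44L. An excess over independent lists was not particular to the cytokines. NF-kB block and IL-10 in OCI-Ly3 both raised 135 genes (65.6), while 45 rose with NF-kB block and fell with IL-10 (77.2). A dye bias common to the experiments would enter both lists, so independent lists can be too low a baseline. Genes higher with IL-6 were higher with IL-10 as a set (114 genes, median 0.058, adjusted p = 5.92e-07; adjusted p = 0.0169 with an estimated correlation). In all, 346 of 3644 genes differed (204 higher with IL-6, 142 lower). With the replicate number as a block 134 differed (64 higher, 70 lower), with the run as a block 103 (51 higher, 52 lower), and without the 24 h array of IL-6 196. Cytokine, line and array run change together here, so none of them can be separated from the others.

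STAT3 siRNA in OCI-Ly10 lowered STAT3 by 1.59 ± 0.17 (log2 -1.59, adjusted p = 6.4e-05, 4 of 4 arrays), and GZMB and GZMH, which encode granzymes, were lower with it. The control had no siRNA, so general or off-target effects of siRNA cannot be told from those of lower STAT3. GZMB fell by 1.09 ± 0.16 (adjusted p = 0.00165), GZMH fell by 0.82 ± 0.13 (adjusted p = 0.00467), DHRS9, a retinol dehydrogenase, fell by 0.82 ± 0.09 (adjusted p = 8.77e-05) and GPR183 fell by 0.73 ± 0.13 (adjusted p = 0.00562), each on 4 of 4 arrays. CCL4 rose by 0.80 ± 0.10 (adjusted p = 0.000487), the surface glycoprotein CD52 by 0.70 ± 0.11 (adjusted p = 0.00373) and the histone gene H2BC12 by 0.57 ± 0.08 (adjusted p = 0.000487), each on 4 of 4. IFI44L (0.52 ± 0.12) and CCL3 (0.48 ± 0.11) rose on 4 of 4 arrays and lost their calls with the run as a block (adjusted p = 0.0599 for both). The same held for the lower genes SOCS2 (-0.65 ± 0.13, adjusted p = 0.0557 with the block) and BCL6 (-0.27 ± 0.07, adjusted p = 0.141 with the block). Of 36 STAT3 targets and feedback genes 3 fell and 0 rose (3 and 0 adjusted over the list alone; 1 and 0 with the run as a block; adjusted p = 0.244). These were STAT3, the siRNA's own target, SOCS2 and BCL6, and the 1 left with the run as a block was STAT3. No list passed against 0 with the siRNA. Against the other 5 experiments, at the preset correlation, 4 lists passed. NF-kB targets were higher (adjusted p = 1.08e-06) and the MYC-linked list was higher (adjusted p = 0.0195), while MHC class II genes (adjusted p = 0.00635) and STAT3 targets (adjusted p = 0.0275) were lower. Their medians with the siRNA itself were 0.072, 0.084, 0.0071 and -0.039 in that order. The subtracted experiments include the NF-kB blocks, which lowered NF-kB targets, and IL-10, which raised MHC class II genes and STAT3 targets. These shifts therefore follow in part from the construction and are not taken as effects of the siRNA. SOCS3 (0.19, adjusted p = 0.438) and NFKBIA (0.23, adjusted p = 0.308) did not pass. Genes that IL-6 raised were low with the siRNA as a set (112 genes, median -0.066, adjusted p = 0.00207), but not with an estimated correlation (adjusted p = 0.175). Of these, 11 were called lower (2.08 for independent lists), among them GZMB, GZMH, GPR183 and DHRS9. Only 3 were so called with the run as a block (0.226), among them GZMB and GPR183. In all, 144 of 4346 genes passed (55 higher, 89 lower), 48 with the run as a block (12 higher, 36 lower). The count was 21 without replicate 1 of 24 h and 53 without replicate 2 of 48 h. The 2 runs correlated at 0.229 across genes, and fitted on the siRNA arrays alone limma called 0 genes (619 with unadjusted p under 0.05).

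JAK inhibitor I in OCI-Ly10 raised the stress factors DDIT3, ATF4 and ATF5 and lowered DUSP2, GPR183 and BCL3. DDIT3, which encodes CHOP, rose by 1.11 ± 0.08 (adjusted p = 1.63e-07), ATF5 by 0.91 ± 0.12 (adjusted p = 0.000203) and ATF4, the main factor of the integrated stress response, by 0.90 ± 0.14 (adjusted p = 0.00082), each on 4 of 4 arrays. SOCS5 (0.81 ± 0.08, adjusted p = 1.52e-05), XBP1, a factor of the unfolded protein response (0.66 ± 0.09), and the amino acid transporter subunit SLC3A2 (0.68 ± 0.12) rose on 4 of 4 arrays, and the alanyl-tRNA synthetase gene AARS1 (0.83 ± 0.15) on 3 of 3. DUSP2, a MAP kinase phosphatase, fell by 1.08 ± 0.09 (adjusted p = 8.29e-07), MNDA fell by 0.92 ± 0.12 and GPR183 fell by 0.80 ± 0.13 (adjusted p = 0.00169), each on 4 of 4 arrays. CCL4 fell by 0.80 ± 0.10 (adjusted p = 0.000187), BCL3 fell by 0.76 ± 0.09 (adjusted p = 0.000126) and MYC fell by 0.70 ± 0.16 (adjusted p = 0.0213), each on 4 of 4. STAT3 was at -0.69 ± 0.17 (adjusted p = 0.0264, 4 of 4), but adjusted p = 0.079 with the run as a block.

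Of 41 NF-kB targets 6 fell and 0 rose with the inhibitor (10 and 1 adjusted over the list alone; 5 and 0 with the run as a block). Their list had adjusted p = 2.31e-05, and adjusted p = 0.285 with an estimated correlation. It had adjusted p = 0.337 against the other 5 experiments, and NFKBIA was at -0.037 (adjusted p = 0.949). Of 9 sterol synthesis genes 3 fell and 0 rose (4 and 0 adjusted over the list alone), among them IDI1 (-0.64 ± 0.12) and SQLE (-0.52 ± 0.09). The sterol list had adjusted p = 0.00147, and adjusted p = 0.27 with an estimated correlation. Interferon-stimulated genes were lower, with MX1 at -0.36 ± 0.08 (4 of 38 fell, 1 rose; 7 and 2 adjusted over the list alone; 1 and 0 with the run as a block; adjusted p = 0.00416; adjusted p = 0.497 with an estimated correlation). Of 15 genes in the MYC-linked list, MYC and LDHA fell (3 adjusted over the list alone; adjusted p = 0.00423; adjusted p = 0.51 with an estimated correlation). Of 26 immediate-early genes DUSP2, CCL4, MYC and CCL3 fell and 1 rose (5 and 1 adjusted over the list alone; 4 and 0 with the run as a block; adjusted p = 0.00654; adjusted p = 0.27 with an estimated correlation). Of 36 STAT3 targets 6 fell and 3 rose, the same adjusted over the list alone, and 4 and 1 with the run as a block. Their list did not pass against 0 (adjusted p = 0.0811), but was lower against the other 5 experiments (adjusted p = 0.0154 at the preset correlation). IL-10, which is among the subtracted experiments, raised this list (median 0.2393). The latter result therefore follows in part from the construction and is not taken as a fall with the inhibitor. In all, 146 of 4480 genes passed (49 higher, 97 lower), 77 with the run as a block (27 higher, 50 lower), and 9 passed at 3 h against 141 at 6 h. The 2 runs correlated at 0.369 across genes. The count was 44 without replicate 2 of 3 h, 48 without replicate 1 of 3 h and 88 without replicate 2 of 6 h. The share of higher calls, 33.6% with all arrays, was 60.2% (53 higher, 35 lower) without replicate 2 of 6 h and 20.6% (33 higher, 127 lower) without replicate 1 of 6 h, so the balance of direction rested on single arrays.

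**Figure D4:**
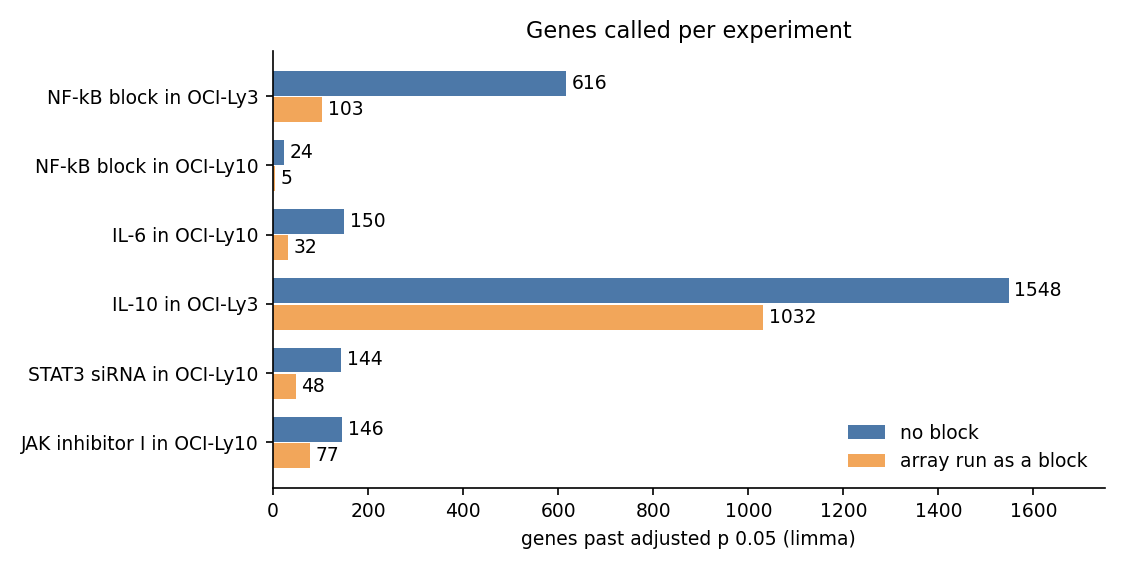
Number of genes past adjusted p 0.05 in limma (x axis) per experiment, without a block and with the array run as a block. The counts run from 24 to 1548 without the block and from 5 to 1032 with it.

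The siRNA and the inhibitor lowered 15 genes in common (1.97 for independent lists), including STAT3, GPR183, DHRS9, MNDA and SAMSN1, and raised CDK10 in common. GPR183 and DHRS9 were among 5 genes that stayed lower with both with the run as a block (0.42 for independent lists), and 0 were higher with both. CCL3 and CCL4, which encode chemokines for monocytes and T cells, rose with the siRNA and fell with the inhibitor, and CCL4 alone did so with the run as a block. Genes lower with the siRNA were low with the inhibitor as a set (88 genes, median -0.21, adjusted p = 7.58e-18; adjusted p = 0.00797 with an estimated correlation). The correlation across 4287 genes was 0.425 (Spearman 0.448), and 0.538 when the experiments outside the pair were subtracted. BCL3, GPR183, DHRS9, SAMSN1, TCF12, ELF3 and CD36 rose with IL-6 and fell with the inhibitor (7 against 3.28 for independent lists), and CCL3, CCL4 and MX1 fell with both. BCL3 and GPR183 (2 against 0.401), and CCL4 and MX1, kept these calls with the run as a block. Between IL-6 and the inhibitor the correlation across 3234 genes was 0.0878, and 0.289 when the experiments outside the pair were subtracted. The former ranged from -0.106 without replicate 2 of the inhibitor's 6 h arrays to 0.245 without replicate 1. Any dye bias of a gene enters both members of each pair. Where outside experiments were subtracted, the same mean left both members, which can itself raise the correlation.

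**Figure D5:**
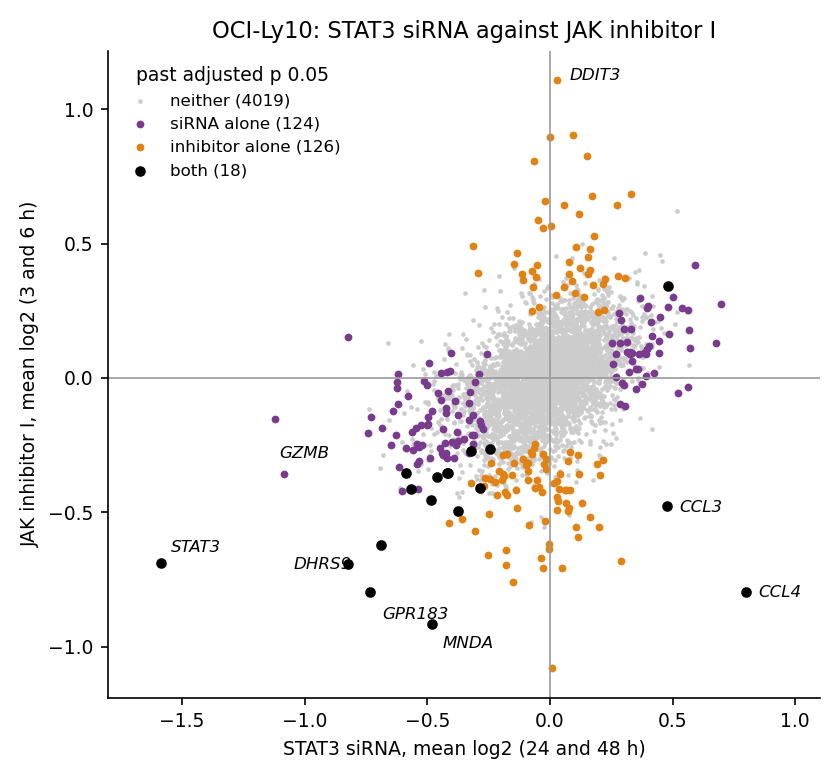
Mean log2 ratio with STAT3 siRNA (x axis, 24 and 48 h) against JAK inhibitor I (y axis, 3 and 6 h) for 4287 genes in OCI-Ly10; colours mark genes past adjusted p 0.05 in 1 or both. GPR183 was at -0.73 and -0.80, CCL4 at 0.80 and -0.80, and DDIT3 rose by 1.11 with the inhibitor.

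Lists that passed in no experiment when tested against 0 were plasma cell differentiation, B cell and germinal centre identity, the BCL2 family, heat shock, p53 targets, and the markers of myeloid and of erythroid and stromal cells (smallest adjusted p = 0.0585). Against the other 5 experiments, myeloid markers (adjusted p = 0.00159), the BCL2 family (adjusted p = 0.0458) and erythroid and stromal markers (adjusted p = 0.0496) were lower with NF-kB block in OCI-Ly3. PRDM1 and IRF4 were the plasma cell genes that rose with IL-10, while 5 of the 16, CD38 among them, fell (6 adjusted over the list alone). BIRC2, an inhibitor of apoptosis (0.94 ± 0.06), and MCL1 were among 7 of 21 BCL2 family and apoptosis genes that rose with IL-10, and 3 fell (9 and 4 adjusted over the list alone). CD14, a lipopolysaccharide co-receptor (0.60 ± 0.09, 10 of 10 arrays), was among 4 of 12 myeloid markers that rose with it, and 2 fell (4 and 0 with the run as a block). Of the other lists, 9 of 30 B cell and germinal centre genes rose and 5 fell with IL-10, 2 of 13 heat shock genes rose and 5 fell (4 and 5 adjusted over the list alone; 2 and 3 with the run as a block), 3 of 12 p53 targets rose and 1 fell (3 and 0 with the run as a block), and 1 of 10 erythroid and stromal markers rose. The counts not given a second value here were the same adjusted over the list alone.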

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

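The tests on amino acid response genes, on dye bias of ribosomal protein genes, on array runs, on the difference between the lines and on splits of the NF-kB arrays were chosen only after the results they bear on were seen.

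Amino acid response genes were higher with JAK inhibitor I: in a list of 44 genes written after DDIT3, ATF4 and AARS1 were seen, 15 of the 26 measured rose and 0 fell (18 and 1 adjusted over the list alone; median 0.425, p = 1.8e-20, and p = 0.00247 with an estimated correlation of 0.435, both inflated by that choice). A dye bias of these genes would raise them in every experiment, but their median over the other 5 experiments was -0.0572, from 0.132 with NF-kB block in OCI-Ly3 (4 rose, 0 fell) to -0.203 with IL-10 (3 rose, 14 fell). A deviation of a single array run is argued against by the lower of the 2 run medians, 0.3306, and 13 rose with the run as a block. Members not past the threshold with the inhibitor included ASNS (-0.072), CTH (-0.279), PPP1R15A (-0.297) and ATF3 (0.080). A lower STAT3 level as the route is argued against by a median of 0.001971 with the siRNA, at later times than with the inhibitor. A direct stress response to the compound, an early effect of lower STAT3, or an effect of JAK inhibition that does not pass through STAT3 amount may account for the pattern. No other inhibitor or dose was measured to tell these apart.

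Ribosomal protein genes lay above 0 in most experiments. Their median was above 0 on 35 of 40 arrays (-0.091 to 0.419), also at 30 min of IL-6 (0.2615), as a dye bias of abundant transcripts would give. A dye bias equal in all experiments may account for part of their rise in OCI-Ly3. Against the other 5 experiments the list was still higher (adjusted p = 0.000873 in limma at the preset correlation). Its median there, 0.2853, lay above the 0.06844 to 0.1503 of the others. That test was not run at the list's estimated correlation of 0.3986, at which the list did not pass against 0 (adjusted p = 0.115). Whether such a bias accounts for all of the rise is therefore not decided. A response growing after doxycycline was tested on OCI-Ly3: the list's rise from 1 h to 2 to 6 h was 0.1449, above the bound of 0.1 set beforehand. The spread used to judge this rise, chosen after that value was seen, was 0.1253 (SD of the 8 later arrays' medians), and 1 h had 1 array. By array the medians were 0.1225 at 1 h, 0.3652 at 1.5 h, 0.0525 and 0.419 at 2 h and 0.2915 at 3 h. They were 0.3 and 0.4107 at 4 h and 0.257 and 0.1643 at 6 h, so they did not grow steadily with time. The test therefore does not decide, and a response to the block is left open.

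NF-kB block called 616 genes in OCI-Ly3 and 24 in OCI-Ly10. Fits with 3 OCI-Ly3 arrays, which also left out the 2 h arrays, gave 46 to 214 genes in the 4 choices. These counts were well below 616 but above the bound of 36. The number of arrays may thus account for part of the gap. Whether it is the whole cause is not decided. No time point of OCI-Ly10 was replicated, so its test took its spread from other experiments, which may not match that of its own arrays. The spread of the arrays differed as well, with SDs of 0.1182 to 0.2567 in OCI-Ly10 and 0.1948 to 0.3576 in OCI-Ly3. With arrays scaled to equal spread the counts were 238 in OCI-Ly10 and 583 in OCI-Ly3, so the size of the gap depends on the scaling. Deviations shared within a run could add to it: with the run as a block OCI-Ly3 kept 103 of its calls and OCI-Ly10 kept 5. A difference between the lines stays open, since the test of the difference called 0 genes (108 with unadjusted p under 0.05 in limma). In all 35 splits of these 7 arrays the count was at least that 0 (highest other 10, in a split that put 1 OCI-Ly3 array with 3 of OCI-Ly10), so chance is not excluded and the splits decide nothing.

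IL-6 in OCI-Ly10 and IL-10 in OCI-Ly3 differed in 346 genes by the test of the difference. With time points pooled, the real split of the 15 arrays gave 310 genes and 1 of 100 splits, the real one, gave as many (highest other 28), and line, cytokine and run change together in that split.

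A test of later against earliest time points called genes in 4 experiments. In all but IL-10 the earliest time had 1 array and no spread of its own, so those calls can reflect that array alone and are not taken as differences in time. NF-kB block in OCI-Ly3 gave 2 genes, NFKBIA (-1.60 later minus 1 h) and CCL25 (2.13, owing to a value of -2.22 on the 1 h array), the latter named here only after its values were seen. IL-6 gave 18 genes (10 higher later, 8 lower), with SOCS3 the lowest at -1.85. IL-10 gave 181 (120 higher, 61 lower), with CXCL9 at 2.21 and DUSP5, an ERK phosphatase, at -1.76. The siRNA gave 5 (4 higher, 1 lower), which were TBRG1, CBLL1, RFXAP, HNRNPA1L2 and HROB, named after their values were seen.

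Probes without a gene symbol, left out of the gene tests, also passed the threshold: 452 of 4211 with NF-kB block in OCI-Ly3, 20 of 4619 with it in OCI-Ly10, 31 of 2264 with IL-6, 1129 of 4075 with IL-10, 123 of 4017 with the siRNA and 38 of 4428 with the inhibitor. With the run as a block these were 45, 4, 0, 620, 22 and 21. For IL-6 1.37% of unnamed probes passed against 4.54% of named genes, and for the inhibitor 0.858% against 3.26%.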

How the results depend on the processing

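The run block (also for list tests and for overlaps of called genes) and the fit without the 2 h arrays were chosen after seeing the data; the other alternatives were planned. Of 202 calls of named genes, 36 passed under every alternative with a value and 181 kept their direction under all of them. The directions that turned, in calls and in values not past the threshold, are listed below; the cause was not tested for any change below, except that leaving out arrays or fitting an experiment alone leaves fewer arrays. Channel intensities were not used, so what signal over background limits could not be tested. Leaving out arrays where a time point then had none tested the remaining times; NF-kB block in OCI-Ly10 was not fitted alone, since 1 mean per time point leaves no residual degrees of freedom there, and has no value.

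Counts that moved by over 1.5 times were these. NF-kB block in OCI-Ly3 (616): 368 fitted alone, 303 with the replicate number as a block, 103 with the run as a block, 371 without the 2 h arrays and 2 against the earliest time point. NF-kB block in OCI-Ly10 (24): 238 with arrays scaled, 38 with array weights, 10 with all time points, 10 against the other 5 experiments, 0 against the earliest time point (25 with unadjusted p under 0.05 in limma) and 5 with the run as a block. IL-6 (150): 455 scaled, 83 with 1 probe per gene, 71 alone, 289 with array weights, 79 with the replicate number as a block, 309 against the other 5, 18 against the earliest time point and 32 with the run as a block. IL-10 (1548): 1031 alone, 765 against the other 5 and 181 against the earliest time point. STAT3 siRNA (144): 83 scaled, 257 with 1 probe per gene, 0 alone (619 with unadjusted p under 0.05 in limma), 88 with array weights, 48 with the replicate number and 48 with the run as a block, 643 with all time points, 95 against the other 5 and 5 against the earliest time point. JAK inhibitor I (146): 232 scaled, 12 alone, 226 with array weights, and 77 with the replicate number or the run as a block. The difference between the lines (0) was 2 with arrays scaled. IL-6 minus IL-10 (346) was 207 on those 2 experiments alone, 134 with the replicate number and 103 with the run as a block; its share of higher calls, 59%, was 47.2% with a value on every array, 48% with 1 probe per gene, 47.8% with the replicate block and 49.5% with the run block. Of the 26 list tests past the threshold, 5 passed with an estimated correlation and 20 against the other 5 experiments, where 14 other list tests passed as well (34 in all). Those not given with their experiment were STAT3 targets (adjusted p = 0.0424 in limma, lower) and sterol synthesis (0.0065, higher) with NF-kB block in OCI-Ly3, STAT3 targets with it in OCI-Ly10 (4.68e-06, lower), NF-kB targets (7.84e-05, higher) and interferon-stimulated genes (0.00616, lower) with IL-6, and NF-kB targets with IL-10 (0.0061, higher). By construction a list that the other experiments moved is shifted the opposite way in this test, as NF-kB targets are by the NF-kB blocks. The correlation of siRNA and inhibitor (0.425) was 0.538 against the experiments not in the pair, that of NF-kB block in both lines (0.348) was 0.531, and that of IL-6 and inhibitor (0.0878) was 0.289. Subtracting 1 shared mean from both members can raise these values by construction.

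Leaving out 1 array gave, lowest and highest, 269 and 957 genes for NF-kB block in OCI-Ly3 (without 6 h replicate 1 and 2 h replicate 1), 1 and 17 in OCI-Ly10 (without 24 h and 3 h), 93 and 147 for IL-6, 1161 and 1569 for IL-10, 21 and 106 for the siRNA, 44 and 160 for the inhibitor, 0 and 0 for the difference between the lines and 196 and 423 for IL-6 minus IL-10. Correlations across genes ranged from -0.106 to 0.245 (IL-6 and inhibitor), 0.308 to 0.417 (siRNA and inhibitor) and 0.164 to 0.49 (NF-kB block in both lines).

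Signs of named genes turned as follows. Against the other 5 experiments: STAT3 0.022 and HLA-DMB -0.068 (NF-kB block in OCI-Ly3), TNF 0.088 (IL-6), SOCS3 -0.024 (siRNA) and NFKBIA 0.37 (inhibitor). The subtracted mean holds treatments that move some of these genes, as IL-10 lowers TNF and the siRNA lowers STAT3, so such turns follow in part from the construction. Against the earliest time point, NF-kB block in OCI-Ly3: HSPA1A 0.024. With IL-6: NCL 0.93, LBR 0.58, KEAP1 0.18, CDK12 0.060, NFKBIA -0.27, IL6 -0.13, IL10 -1.27, LCK -0.0081, NDRG1 -0.27 and SOCS3 -1.85. With IL-10: RPS21 -0.064, TP53I3 -0.023, IL6 -0.25 and JUN -0.34. With the siRNA: STAT3 0.40, PLSCR1 0.75, TTK 0.030, BCL6 0.10, IL6 0.14, PFKP -0.13, CCL3 -0.065 and IFI44L -0.42. With 1 probe per gene: SOCS3 0.072 (NF-kB block in OCI-Ly10), NFKBIA -0.032 (IL-6) and IL6 0.12 (siRNA). As deposited: NFKBIA -0.0021 (IL-6). With all time points: STAT3 -0.0071 (IL-6) and IL10 -0.27 (siRNA). Leaving out 1 array: NFKBIA -0.014 to 0.029 (IL-6) and -0.11 to 0.032 (inhibitor), IL6 -0.084 to 0.048 and IL10 -0.18 to 0.32 (siRNA), none of which passed the threshold with all arrays.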

Other observations

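CCL4 was chosen after its values were seen as a gene whose direction differed between treatments of OCI-Ly10. It rose with NF-kB block (0.82) and with STAT3 siRNA (0.80) and fell with IL-6 (-0.44) and the JAK inhibitor (-0.80); in OCI-Ly3 it was at -0.12 with NF-kB block and -0.02 with IL-10, neither past the threshold. With the inhibitor CCL4 was at -1.23 at 3 h and -0.36 at 6 h (2 arrays each). With IL-6 it was at 0.45 at 30 min (1 array) and -0.99 at 24 h (1 array). CCL3 had the same directions in the siRNA (0.48), IL-6 (-0.32) and inhibitor (-0.48) experiments, and was at 0.54 with NF-kB block in OCI-Ly10 (adjusted p = 0.0576 in limma, 3 of 3 arrays). IFI44L fell with IL-6 (-0.71) and IL-10 (-0.31) and rose with the siRNA (0.52).

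MYC, which drives growth, was at -1.16 on the 8 h siRNA array, a time outside the window. That array, with no spread of its own, had 236 genes past the threshold (58 higher, 178 lower), against 2 at 24 h and 83 at 48 h with 2 arrays each. IL-10 lowered 14 of the 26 measured amino acid response genes and raised 3 (median -0.203), with ATF4 at -0.46 and AARS1 at -0.35, the opposite direction to the inhibitor in the other line.

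Of 3110 genes tested in all 6 experiments, 358 (11.5%) had the same sign in each, 188 higher and 170 lower, where 6 independent signs would give 3.12%. The experiments include treatments with opposite aims on STAT3.

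The design text speaks of replicates of each time point, while 12 of the 26 time points here had 1 array.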
